A study of Mus musculus with 8 samples.

How the data were processed

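Gene expression was measured in CD4 T cells sorted by flow cytometry from the spleens of female mice aged 8 to 12 weeks. The mice were either wild type C57BL/6 (WT) or lacked the aryl hydrocarbon receptor gene Ahr on a background backcrossed to that strain (KO). They received an intraperitoneal injection of 10 µg/kg TCDD, the prototypical ligand of this receptor, or its DMSO solvent, and were killed after 24 h. Each of the 4 groups (KO DMSO, KO TCDD, WT DMSO, WT TCDD) had 2 arrays, and each array carried RNA pooled from 4 animals, so 8 arrays were analysed. Per the labels' protocols, RNA was isolated with TRIzol, amplified with the Ambion MessageAmp kit and processed by the Affymetrix standard procedure for the MOE430A mouse array.

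The values analysed here were the deposited log2 expression values, made by the authors with RMA (robust multi-array averaging, which corrects background, normalises the arrays to each other and summarises the probes of a set) from the affy package, per the submitters' processing notes. Versions of both were not given in the sources used here. The log2 unit was checked against the deposited values, whose array medians lay between 6.08 and 6.15. The table held 22690 probe sets, of which 64 Affymetrix controls were left out and 22626 were tested. A probe set is a group of short probes for 1 transcript region, and a gene can have several. In the array annotation used here, 20380 tested probe sets had 1 gene symbol, 691 had several and 1555 had none. Of those with 1 symbol, 20351 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table served only for names and for the order of genes along a chromosome, and no coordinates are given because no build is stated for the array. No gene is named from a probe set with several symbols.

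Samples were grouped by their titles. The array titled WT TCDD replicate 1 has a free-text description that names the knockout, while its title, source and strain entries name the wild type, and it was analysed as WT. Whether any arrays were processed together is not given in the sources used here, so no processing batch could be modelled. Arrays carry no read depth, and their number limits the precision. No pair of arrays was a duplicate: at most 2.85% of probe sets had identical values in any pair.

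Comparisons were fitted with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes). KO was compared with WT over all 8 arrays as 4 against 4, because the series' design text pools treated and solvent arrays for this comparison. TCDD was compared with DMSO within each genotype, and the difference of these effects was tested as an interaction, in a model of 4 group means. P-values were adjusted over all tested probe sets by the Benjamini-Hochberg method (BH), and an adjusted p under 0.05 was called. Single levels were also compared by an exact two-sided permutation test over the 70 arrangements of 4 KO and 4 WT arrays. The 22 gene lists, fixed beforehand, were tested with limma's camera on 1 probe set per gene (the one with the highest mean, over 12393 genes), with a preset correlation between genes of 0.01 and with an estimated correlation beside it, and BH adjustment over the lists. Lists needed at least 5 measured genes. The tests, the alternatives, the lists and the rule for naming genes were set before the data were examined, except where the text says otherwise.

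The genes named for KO against WT were Ahr, the 12 largest rises and 12 largest falls among called probe sets whose KO arrays all lay on 1 side of all WT arrays (1 probe set per gene), and up to 4 members per list past adjusted p 0.05 over all probe sets or over the list alone. For TCDD and the interaction, with fewer than 5 calls, they were up to 5 probe sets per direction with unadjusted p under 0.001, given as values that did not pass, and always Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1. A few markers (Cd4, Cd3e, Cd79a, Cd8a, Lyz2, Hba-a1) were given as levels. Tiparp in KO against WT, further called members of the lists and the haemoglobin probe sets were singled out after their values were seen.

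The fits were tested on simulated data with the means and variances of the 22626 probe sets, with 200 changed per run over 20 runs. For KO against WT, 32.1% of changes of 0.50 log2 were recovered, 85.5% of changes of 1 and 98.3% of changes of 2, and 4.96% of calls were false. For TCDD in WT the recovered shares were 0.821%, 48.8% and 92.3%, with 6.13% of calls false. The simulated noise was independent between probe sets and arrays, without the variation that the real arrays share. These shares therefore hold for that setting and may differ in the data.

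Alternatives were a replicate block, another quantile normalization, median centring, leaving out probe sets with a mean under the median of 6.13, eBayes with trend and robust settings, array weights, each array left out in turn, other models and array subsets, other thresholds, genes in place of probe sets and, for lists, an estimated correlation or the mean of all probe sets of a gene. After the data were seen, fits without both WT arrays numbered 2 and with an RNA quality covariate (the log2 difference of the actin control probe sets near the transcript's 3′ and 5′ ends) were added. Lists of markers for plasmacytoid dendritic cells, conventional dendritic cells, red pulp macrophages, B cells, neutrophils and NK or CD8 T cells, used in the last part, were also added then; 8 genes were taken off the plasmacytoid list before its test, as members of earlier lists, T cell genes or not on the array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.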

Results

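The data comprised 8 arrays of splenic CD4 T cells, 2 in each of 4 groups: WT and Ahr knockout (KO) mice given DMSO or TCDD. Each array held RNA pooled from 4 animals, and the labels call the 2 arrays of a group biological duplicates. The correlation between 2 arrays of a group ranged from 0.967 to 0.992 over 22626 probe sets, and that between arrays of different genotype from 0.937 to 0.989. The first principal component held 52.1% of the variance. On it the 4 KO arrays lay between −36.2 and −5.20, the WT arrays numbered 1 at 9.10 (DMSO) and −2.04 (TCDD), and the WT arrays numbered 2 at 49.2 (DMSO) and 40.4 (TCDD). The log2 difference between the actin control probe sets at the 3′ and 5′ ends, a measure of RNA integrity, was 3.66 ± 0.15 in KO and 3.62 ± 0.71 (SD, n = 4 each) in WT. It ranged from 3.48 to 3.82 in KO and from 2.90 (WT DMSO replicate 2) to 4.56 (WT TCDD replicate 1) in WT. The same difference for Gapdh was 4.95 ± 0.19 in KO and 4.62 ± 0.73 in WT (SD, n = 4 each; exact permutation p = 0.457), lowest on the WT arrays numbered 2 (3.71 and 4.35).

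**Figure D1:**
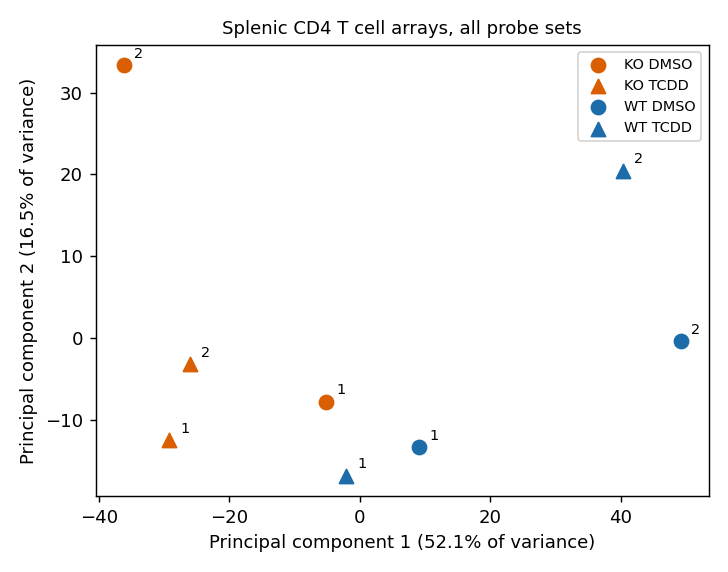
Scores of the 8 arrays on principal components 1 and 2 of the log2 values of all probe sets, in arbitrary units, with the share of variance on each axis. Colour gives the genotype, shape the treatment and the digit the replicate number. The 4 KO arrays lie between −36.2 and −5.20 on component 1 and both WT arrays numbered 2 lie above 40.

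The targeted gene, Ahr, encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor. Of its 2 probe sets, 1 read 6.74 ± 0.26 in KO and 6.21 ± 0.10 in WT (SD, n = 4 each), a log2 difference of 0.53 (SE 0.13) that was higher in 4 of 4 KO arrays and did not pass (limma, BH adjusted p = 0.0658; exact two-sided permutation p = 0.0286, the smallest 70 arrangements allow). The other read 6.52 ± 0.23 in KO and 6.48 ± 0.14 in WT (limma, BH adjusted p = 0.906). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so neither reading checks the genotype labels. Tiparp, an inducible target of the receptor, was singled out after its values were seen. Of its 3 probe sets, 1 read 6.39 ± 0.05 in KO and 7.53 ± 0.18 in WT and fell by 1.15 on the log2 scale (limma, BH adjusted p = 0.00424), with the WT TCDD replicate 1 array, whose description names the knockout, at 7.35. Another fell by 0.46 (limma, BH adjusted p = 0.0438), and the brightest read 8.83 ± 0.29 in KO and 9.02 ± 0.60 in WT and did not pass (limma, BH adjusted p = 0.767).

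Among the 12 largest rises in KO were Irf8, a transcription factor of myeloid and dendritic lineages (9.65 ± 0.40 in KO, 6.68 ± 0.62 in WT, log2 difference 2.97), Cd74, the class II invariant chain (10.31 ± 0.91 and 7.55 ± 0.43, difference 2.76), and Tyrobp, a signalling adaptor of myeloid and natural killer (NK) cells (10.10 ± 0.52 and 7.61 ± 0.13, difference 2.49; SD, n = 4 each). The lysosomal cathepsins Ctsl, Ctsz and Ctsh rose by 2.70, 2.47 and 2.46, and Mpeg1 (a macrophage pore-forming protein), Grn (progranulin) and Ly86 (which pairs with a Toll-like receptor homologue) rose by 2.27, 2.16 and 2.14. The kallikrein Klk1 and the chemokine receptor Ccr9 rose by 3.02 and 2.16, and the unnamed transcript D13Ertd608e by 3.55 with a wide WT spread (6.77 ± 1.56). The adjusted p of these 12 ran from 0.0032 to 0.0385 (limma, BH). Each was higher in 4 of 4 KO arrays than in any WT array, which the rule that picked these genes requires.

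Among the 12 largest falls in KO, Cnot7, a subunit of the CCR4-NOT deadenylase, fell by 2.07, from 8.88 ± 0.60 in WT to 6.80 ± 0.24 in KO, and Ankhd1 fell by 1.90, from 8.89 ± 0.51 to 6.98 ± 0.17 (SD, n = 4 each). Nfx1 (−1.81), the nuclear exonuclease Xrn2 (−1.79), the exosome helicase Mtrex (−1.75), Pdcl (−1.73), Zmym5 (−1.70) and Sox4, a transcription factor of lymphoid progenitors (−1.68), fell as well. So did Naa15 (−1.64), Ppm1b (−1.56), Wac (−1.54) and Nupl1 (−1.46). Their adjusted p ran from 0.00977 (Ankhd1) to 0.0482 (Sox4) (limma, BH). In all 12, the WT array numbered 2 read above the WT array numbered 1 within each treatment; these arrays stood apart on the first principal component and had the lowest actin (2.90 and 3.30) and Gapdh (3.71 and 4.35) differences. Of these 12 genes, 11 had other probe sets. Another one was called in the same direction for 3 of them (Naa15, Wac and Nupl1).

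In all, limma called 631 of 22626 probe sets between KO and WT, 360 higher and 271 lower in KO (288 and 231 genes, 2 of them with probe sets in both directions). Of these, 122 were at least 2-fold higher and 72 at least 2-fold lower. The balance of directions depended on the setting: 375 higher and 184 lower after median centring, but 424 and 460 with dim probe sets left out, 248 and 318 without KO DMSO replicate 1, 288 and 379 without WT TCDD replicate 1, and 709 and 1125 with the actin covariate. The count fell to 362 without KO DMSO replicate 2, 119 without KO TCDD replicate 1, 109 without KO TCDD replicate 2, 420 without WT DMSO replicate 1, 124 without WT DMSO replicate 2, 126 without WT TCDD replicate 2, 28 without both WT arrays numbered 2 and 161 in the model of 4 group means. From the DMSO arrays alone it was 0, with 2384 at an unadjusted p under 0.05, and from the TCDD arrays alone 13.

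**Figure D2:**
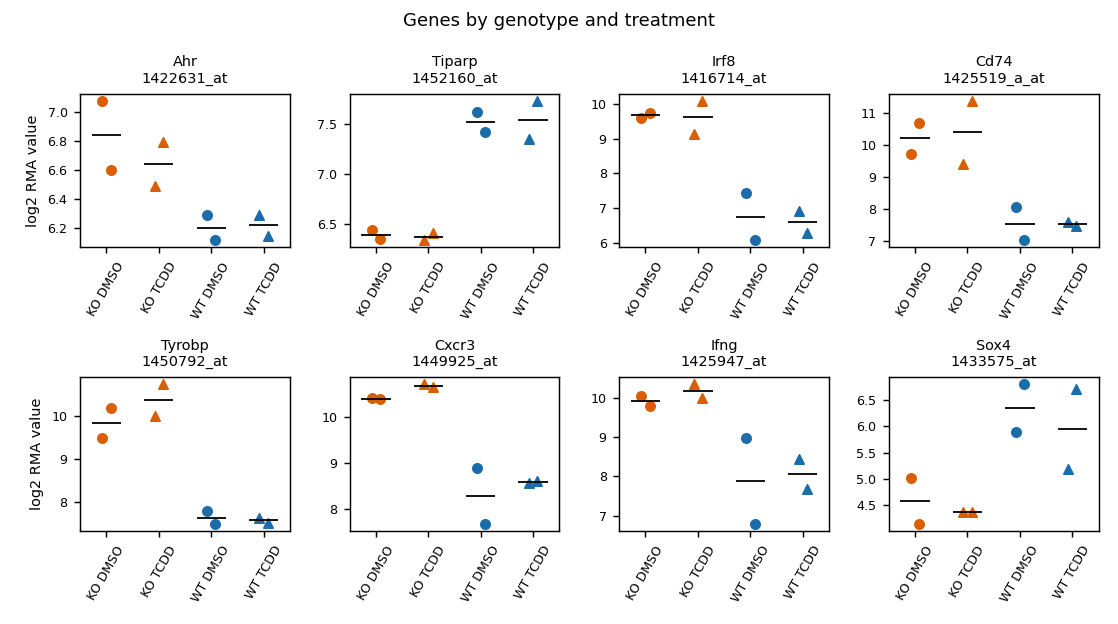
Deposited log2 RMA values of 8 probe sets on each of the 8 arrays, by group; points are arrays, bars are means of 2 arrays, colour gives the genotype, and each panel has its own axis, which does not start at 0. Every KO array lies above every WT array for Ahr, Irf8, Cd74, Tyrobp, Cxcr3 and Ifng and below for Tiparp and Sox4. Irf8, Cd74, Tyrobp and Sox4 were picked by a rule that requires this. Ahr did not pass the test (limma, BH adjusted p = 0.0658).

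Among the T cell lists, few genes passed singly, and no list call held with an estimated correlation. Of 16 measured naive and resting genes, 2 fell, the transcription factors Foxo1 (−1.23, limma, BH adjusted p = 0.034) and Satb1 (−0.65, adjusted p = 0.0392), and 0 rose. Adjusted over the list alone, 8 were lower, among them Bach2 (−1.15), Nsg2 (−0.70) and S1pr1 (−0.69), a receptor for lymphocyte exit from tissues. Ccr7, a homing receptor of the same list, read 0.81 higher and did not pass. Of 13 Th1 genes, 3 rose: the chemokine receptor Cxcr3 (by 2.12), interferon gamma, Ifng (by 2.08), and the chemokine Ccl5 (by 1.22). Adjusted over the list alone, 6 were higher and 1 lower, and Tbx21, the Th1 master regulator, read 1.07 higher (BH adjusted p over all probe sets 0.0638). Of 32 activation and memory genes, 4 rose (Cxcr3, S100a4 by 1.09, S100a6 by 0.94 and Anxa2 by 0.67). Adjusted over the list alone 8 were higher and 2 lower, with Myc at −0.86. Of 18 regulatory T cell genes, Klrg1 (by 1.31) and Ebi3 (by 0.52) rose, and 6 were higher adjusted over the list alone, including Tnfrsf18 (0.79) and Tnfrsf4 (0.71). Of 35 cell cycle genes, 5 rose (Cdk1 by 0.81, Birc5 by 0.56, Aurka by 0.46, Mcm5 by 0.44 and Plk1 by 0.38) and 11 were higher adjusted over the list alone, including Rrm2 (1.25) and Top2a (0.51).

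Limma's camera called these lists at adjusted p = 0.000558 (naive, lower), 0.00945 (Th1), 0.0172 (activation and memory), 0.0172 (regulatory) and 0.000104 (cell cycle), all BH. None held with an estimated correlation, where the adjusted p was 0.305 for the naive, Th1, activation and cell cycle lists and 0.373 for the regulatory list. Of 18 alternatives each, the activation list was lost in 4 and the regulatory list in 5, including leaving out KO DMSO replicate 1, and the regulatory list also without WT DMSO replicate 2. The medians over the genes of a list were −0.61, 0.22, 0.24, 0.15 and 0.28 in the same order, and −0.28, 0.23, 0.18, 0.01 and 0.13 without both WT arrays numbered 2, a fit chosen after the data were seen. Foxo1, Bach2, Nsg2 and S1pr1 read higher, and Ifng, Tbx21, Rrm2 and Tnfrsf4 lower, on the WT arrays numbered 2 than on number 1 in both treatments, and without these arrays Foxo1 (−1.05) and Ifng (1.34) no longer passed. The list of the T cell receptor complex and CD4 identity was not called (adjusted p = 0.993). In it Cd6 rose by 0.82 and Cd5 read 0.90 higher (0.0644), while Cd4 read 8.16 ± 0.09 in KO and 8.37 ± 0.28 in WT and Cd3e 9.36 ± 0.17 and 9.53 ± 0.09 (SD, n = 4 each; limma, BH adjusted p = 0.452 and 0.395).

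Some markers of other cell types were higher in KO too. Of 33 myeloid and dendritic cell markers, 9 rose and 0 fell, among them Tyrobp, Cd68 (by 1.87), Bst2 (by 1.82) and the complement gene C1qb (by 1.74), and 10 were higher adjusted over the list alone. Of 26 B cell and plasma cell markers, 8 rose and 0 fell, 4 of which were genes of class II antigen presentation, shared by dendritic cells: Cd74, H2-Ab1 (by 2.11), H2-Aa (by 1.72) and H2-Eb1 (by 1.70). The others were Spib (by 1.66), Ly6d (by 1.59), Cd37 (by 0.83) and Fcrla (by 0.61), 11 were higher adjusted over the list alone, and the B cell receptor component Cd79a read 5.59 ± 0.20 in KO and 5.67 ± 0.05 in WT (limma, BH adjusted p = 0.715). Of 21 NK and CD8 T cell markers, Nkg7 (by 1.38), Klrg1 (by 1.31), Ccl5 (by 1.22) and Fcer1g (by 0.84) rose, 5 were higher adjusted over the list alone, and both Cd8a probe sets were at 5.77 or lower in either genotype. The camera adjusted p of the 3 lists was 0.000166, 5.53e-05 and 0.0172 (limma, BH). With an estimated correlation the adjusted p of each was 0.305. The macrophage lysozyme Lyz2 read 7.49 ± 0.56 and 7.36 ± 0.61 (limma, BH adjusted p = 0.875).

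**Figure D3:**
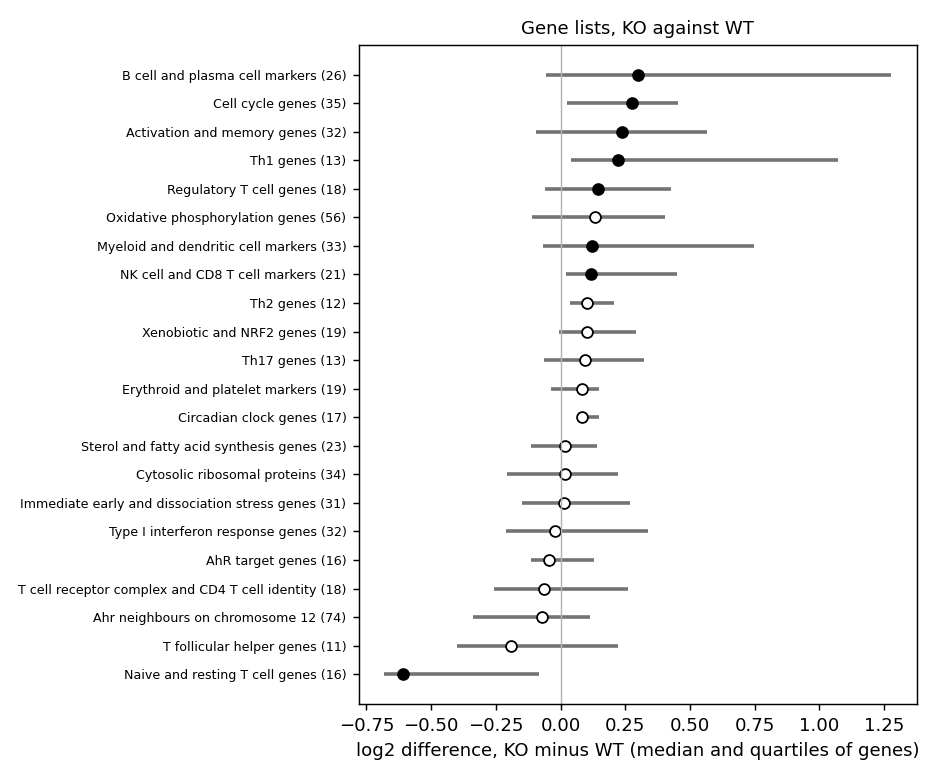
Log2 difference between KO and WT over the genes of each of 22 lists; the point is the median, the bar runs from the lower to the upper quartile, and the number of measured genes stands in brackets. Filled points mark the 8 lists with a camera adjusted p under 0.05 at the preset correlation (limma, BH), of which the naive and resting list is the 1 that lies lower in KO, with a median of −0.61; none of the 8 passed with an estimated correlation.

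The remaining lists were not called in KO against WT, although 3 were in some alternatives, as given below. AhR target genes had a median of −0.05 over 16 genes (camera adjusted p = 0.993), with 1 rise, the transglutaminase Tgm2 (by 1.85), which macrophages also express. Tiparp, a member of this list, entered it by its brightest probe set (−0.19) and not by those called lower in KO. Of 74 genes that neighbour Ahr on chromosome 12, Pik3cg (by 1.14) and Id2 (by 1.09) rose and Snx6 (−1.18) and Lpin1 (−0.90) fell, and 3 were higher and 11 lower adjusted over the list alone (camera adjusted p = 0.0636, and called lower with the mean of all probe sets of a gene, 0.0102, and without KO DMSO replicate 1, 0.0408; the other Pik3cg probe set was called in the opposite direction). Among type I interferon response genes, Bst2, Ifi27l2a (by 0.74), Oas1a (by 0.60) and Zbp1 (by 0.54) rose, Ifit2 read −1.30 and Ifit1 −0.66, and the list's adjusted p was 0.626. Th17 genes (0.38) included Tmem176b, which rose by 1.37, Tmem176a (0.94, not passed) and Il6st, which fell (−0.96). T follicular helper genes (0.684) included Cxcr5, which rose by 0.63, Icos (−0.58) and Pdcd1 (0.34), the last a pair that passed over the list alone. Xenobiotic and NRF2 genes (0.0833, and called higher without KO DMSO replicate 2, 0.0485) held Gstp1, which rose by 0.37, sterol genes (0.993) Dhcr7, which fell (−0.64), and clock genes (0.38) Nr1d2, which fell (−1.02). Oxidative phosphorylation genes (0.0792, and called higher with array weights, 0.0053, without KO DMSO replicate 2, 0.00219, without WT DMSO replicate 2, 0.00663, and without both WT arrays numbered 2, 0.000818) included Ndufa3 and Uqcrb, which rose by 0.61 and 0.40. In the probe sets used for the list, Ndufs4 (−0.84), Cox7c (−0.72), Ndufs8 (0.69) and Sdhb (0.66) passed only over the list. Of the 5 other Ndufs8 probe sets, 2 were called higher in KO over all probe sets. Cytosolic ribosomal proteins (0.993) included Rps9, which rose by 0.55, and Rps28, which fell (−0.39). Th2 (0.229), immediate early (0.727) and erythroid genes (0.4) had 0 calls. The values in brackets after list names are camera adjusted p (limma, BH).

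TCDD for 24 h left the measured transcriptome of WT CD4 T cells without a single called probe set. None of the classical receptor targets was called (n = 2 arrays each; limma, BH adjusted p = 0.997 for each). Cyp1a1, the xenobiotic oxidase, differed from solvent by 0.13 (SE 0.10) and Nqo1 by 0.15 (SE 0.12). Cyp1b1 differed by 0.14, 0.04 and 0.02 in its 3 probe sets, and Tiparp by 0.03, 0.02 and −0.01. Ahrr, the receptor's repressor, differed by 0.43 (SE 0.17; 0.21 without WT TCDD replicate 1, the array with the conflicting description, and 0.64 without WT TCDD replicate 2). In WT, Cyp1a1 read 5.86, Ahrr 4.70, Nqo1 4.97 and Cyp1b1 6.08, 3.98 and 5.32 (means of 4 arrays). All of these lie under the median probe set level of 6.13, where background compresses differences, so small responses could be missed. The 3 Tiparp probe sets, at 9.02, 7.53 and 6.79 in WT, lie above that level and also showed no called response. As values that did not pass, Abhd17a read −0.84 and 1 of the probe sets of Ndufs8 −0.78 (limma, BH adjusted p = 0.997). Limma called 0 of 22626 probe sets, 631 had an unadjusted p under 0.05 where 1131.3 are expected by chance, and 5 had one under 0.001, all lower. The count of 631 depended on single arrays: it was 1485 without WT TCDD replicate 2, 1059 and 317 without WT DMSO replicates 1 and 2, 1082 without either KO DMSO array and 367 without either KO TCDD array, with 0 calls by limma each time. The series' design text puts the number affected in WT mice at about 10.

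As a group, the 16 measured AhR target genes lay slightly higher after TCDD in WT, with 15 of 16 positive, a median of 0.13 and 0 called singly (camera adjusted p = 0.0251, limma, BH; adjusted p = 0.675 with an estimated correlation). In KO the same genes had a median of −0.06 (camera adjusted p = 0.297, limma, BH). The difference between genotypes was called at the preset correlation (camera adjusted p = 0.0178, limma, BH) and not with an estimated one (camera adjusted p = 0.688, limma, BH). No other alternative was run for lists of the TCDD effect in KO or of this difference. Camera also called, as lower after TCDD in WT, the naive and resting genes (median −0.16, adjusted p = 0.0446), type I interferon response genes (−0.10, 0.00701), immediate early and dissociation stress genes (−0.15, 0.00349), cytosolic ribosomal proteins (−0.15, 0.000882) and oxidative phosphorylation genes (−0.09, 0.000882; limma, BH), each with 0 genes called. With an estimated correlation the adjusted p of each was 0.675. After another quantile normalization 0 lists were called, and without WT TCDD replicate 1, the array with the conflicting description and the largest actin difference, 0 were called. The AhR target call was lost on leaving out any 1 of the 4 WT arrays, and the naive call in 10 of 16 alternatives, with its direction turned to higher without WT TCDD replicate 1 (adjusted p = 0.991, limma, BH; naive and resting T cell genes). Of the lists not called, 6 were called in some alternative: T cell receptor and CD4 identity genes (lower, in 5), regulatory T cell genes (higher, in 3), and Th1, erythroid, myeloid and NK or CD8 T cell genes (higher, in 1 each, the myeloid list without WT DMSO replicate 2 with adjusted p = 0.000196, limma, BH).

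In KO mice TCDD gave 0 called probe sets as well. The receptor targets read 0.08 (Cyp1a1), −0.12 (Ahrr), 0.14 (Nqo1), 0.07, 0.07 and 0.08 (Cyp1b1) and −0.01, −0.02 and 0.19 (Tiparp) relative to solvent (n = 2 arrays each; limma, BH adjusted p of 1 for each after rounding). Mvb12a, at 0.76, was the 1 probe set with an unadjusted p under 0.001, and 383 had one under 0.05. That count was 3214 without KO DMSO replicate 1 and 189 without KO TCDD replicate 1, with 0 calls by limma in both. Camera called type I interferon response genes (median 0.17, adjusted p = 0.0482) and oxidative phosphorylation genes (median 0.19, adjusted p = 2.36e-06; limma, BH) as higher, and with an estimated correlation the adjusted p of both was 0.745. In the NK and CD8 T cell list, Nkg7 read 0.78 higher and passed over the list alone (adjusted p 0.0388, limma, BH), not over all probe sets.

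The effect of TCDD was not found to differ between genotypes for any probe set. Limma called 0 for the interaction, 628 had an unadjusted p under 0.05 and 9 under 0.001. The count of 628 became 3448 without KO DMSO replicate 1, 1240 without WT TCDD replicate 1, and 332 and 377 without KO TCDD replicates 1 and 2, with 0 calls each time. Those named by rule were lower in the WT effect than in the KO effect: Bicd2 by −1.48, Abhd17a by −1.48, Ppdpf by −1.34, Ndufs8 by −1.30 and Nol12 by −1.18 (limma, BH adjusted p = 0.998 for each, not passed). The receptor targets differed by 0.05 (Cyp1a1), 0.54 (Ahrr; 0.33 without WT TCDD replicate 1), 0.02 (Nqo1), 0.07, −0.03 and −0.06 (Cyp1b1) and 0.04, 0.04 and −0.20 (Tiparp). With 2 arrays in each group, the simulated fit recovered 0.821% of changes of 0.50 log2 for TCDD in WT and 48.8% of changes of 1. Effects of TCDD in WT of that size therefore cannot be excluded. The interaction was not simulated, so the size of a difference between genotypes that it could miss is not known.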

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

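The outlier statistic and the interaction test below were set before the data were examined. The gap between the most distant array and its neighbour, divided by the range of the 4 arrays of a genotype, was above Dixon's 95% critical value in 8 of 160 groups tested for the named probe sets, where chance gives 8. In WT these were Ctsl, with WT DMSO replicate 1 at 7.63 and the others at 7 or lower (gap share 0.913), and C1qb, with WT TCDD replicate 1 at 6.38 and the others from 5.91 to 5.96 (0.894). WT DMSO replicate 2 lay lowest for H2-Ab1, at 7.80 against 8.70 to 8.76 (0.938), and for H2-Eb1, at 8.76 against 9.28 to 9.36 (0.867). In KO, KO TCDD replicate 2 lay highest for Ccr9, at 9.77 against 9.20 to 9.24 (0.930), for Tmem176b, at 9.60 against 8.45 to 8.62 (0.852), and for Dhcr7, at 7.11 against 6.75 to 6.81 (0.833). KO DMSO replicate 2 lay lowest for Ndufs4, at 6.27 against 6.92 to 6.98 (0.915).

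The effect of TCDD differed between genotypes for 4 gene lists at the preset correlation of camera. AhR target genes lay higher in the WT effect (median difference 0.15, limma, BH adjusted p = 0.0178). Type I interferon response genes (−0.21, adjusted p = 0.00123), cytosolic ribosomal proteins (−0.21, adjusted p = 0.0101) and oxidative phosphorylation genes (−0.39, adjusted p = 2.52e-08) lay lower (limma, BH). None passed with an estimated correlation, where the adjusted p was 0.688 for AhR targets, interferon and oxidative phosphorylation genes and 0.756 for ribosomal proteins. Lists for the interaction were not run under another quantile normalization, with arrays left out or under any other alternative. The 6 lists called for TCDD in WT became 0 after another quantile normalization.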

How the results depend on the processing

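Fits without both WT arrays numbered 2 and with the actin difference as a covariate were chosen after the data were seen. Where a TCDD group was left with 1 array, that array was assumed to vary like the others. For KO against WT, 631 probe sets became 985 after another quantile normalization, 1604 with array weights, 1834 with the actin covariate, 161 in the model of 4 group means, 0 from the DMSO arrays alone, 13 from the TCDD arrays alone, 28 without both WT arrays numbered 2, 194 with a 2-fold minimum and 56 at adjusted p under 0.01. Leaving out 1 array gave 109 (KO TCDD replicate 2) to 667 (WT TCDD replicate 1), with 119 without KO TCDD replicate 1, 124 and 126 without WT DMSO and WT TCDD replicate 2, 362 without KO DMSO replicate 2 and 420 without WT DMSO replicate 1. The subsets and the 4-group model leave fewer arrays or degrees of freedom; for the other moves the cause was not tested. The remaining settings stayed within 1.5 times the count. The TCDD comparisons and the interaction kept 0 calls in all settings that adjust p, and an unadjusted p under 0.001 gave 5 (WT), 1 (KO) and 9 (interaction).

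The replicate numbers were not taken to pair the samples: the correlation of same-numbered deviations was 0.626 between the WT groups, 0.117 between the KO groups and −0.293 to 0.216 across genotypes. With the replicate block, 801 probe sets were called for KO against WT, 0 for TCDD in WT, in KO and for the interaction, and 8 and 6 lists.

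The Ahr probe set that read 0.53 higher in KO passed after another quantile normalization (0.54, limma, BH adjusted p = 0.0439) and otherwise stayed on its side of the threshold, with 0.42 to 0.62 on leaving out 1 array. The cause was not tested. The 8 lists called for KO against WT became 0 with an estimated correlation and 7 to 10 on leaving out 1 array. The 6 lists called for TCDD in WT became 0 with an estimated correlation, 0 after another quantile normalization (cause not tested) and 0 (without WT TCDD replicate 1) to 8 on leaving out 1 array.

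Of 114 named gene results, which leave out the Ahr probe set given above, 57 were called. All 57 kept their sign in every setting, which their selection on these arrays largely fixes, 20 stayed past the threshold without each array in turn, and 0 did so in every setting, since the DMSO arrays alone call none. Of the 57 not called, 18 passed in some setting, all of them in KO against WT. The log2 differences of dim probe sets are compressed by background, which arrays do not separate from signal.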

Other observations

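The marker lists and the comparison of plasmacytoid with other markers were chosen after the results were seen. So were the test on other probe sets of a gene and the test with the actin difference. The form without a filter on level of the test on plasmacytoid markers was also chosen then. The tests on the identity of 1 array and on splits of the arrays were set before their own results. So were the 21 plasmacytoid markers given below. Many other markers were members of the fixed lists, whose results had been seen. Among those measured, they were Itgax, most red pulp macrophage markers and every NK or CD8 T cell marker. They also included the neutrophil markers except Csf3r, Cxcr2 and Mmp9, and the B cell markers except Ralgps2. Of 16 red pulp macrophage markers, 5 rose and 0 fell in KO: C1qb rose by 1.74 and C1qc by 0.54, Cd5l, a macrophage-secreted scavenger protein, by 1.51, the colony stimulating factor receptor Csf1r by 1.27 and the ficolin Fcna by 1.05 (limma, BH adjusted p = 0.0277, 0.0236, 0.00465, 0.027 and 0.0109), while Vcam1 read −0.14, Adgre1 0.16 and Hmox1 0.31 and did not pass. Of 11 conventional dendritic cell markers, Flt3 (by 0.88) and Ffar2 (by 1.28) rose, and Sirpa (−0.04), Cd83 (0.02) and Dpp4 (−0.13) were among the 9 that did not pass. Of 21 plasmacytoid dendritic cell markers not looked at before, 5 rose, the lectins Clec10a and Cd209d by 0.96 and 0.64, Pld4 by 1.52, the transcription factor Bcl11a by 1.57 and Dntt by 0.49, and 16 did not pass, among them Pacsin1 (−0.01) and Atp1b1 (−0.77). Over all measured markers, the median log2 difference was 0.29 for 16 red pulp macrophage and 0.21 for 11 conventional dendritic cell markers. It was −0.03 for 15 B cell, 0.02 for 12 neutrophil and 0.10 for 13 NK or CD8 T cell markers. Against 10000 random lists of like expression these medians lay at percentiles 100, 99.2, 23.1, 48.4 and 97.6. The NK or CD8 list, kept to markers that CD4 T cells lack, leaves out Nkg7, Klrg1, Ccl5 and Fcer1g, the called members of the earlier list. That 0 of its 13 were called was therefore known beforehand. The B cell list leaves out Cd74, H2-Ab1, H2-Aa, H2-Eb1, Spib and Ly6d, called higher in the earlier list, whose median was 0.30. Both choices lower the medians and percentiles. Genes of the random lists were drawn singly, while markers of a cell type can move together over the arrays. Such percentiles can therefore overstate how rare a median is. Over markers above the median level in at least 1 array, a filter that admits genes because they rose in KO, the medians were 0.54, 0.27, 0.09, −0.08 and 0.22. Separately, 4 probe sets assigned to several adult haemoglobin genes at once were higher in KO by 2.23 to 3.33. Their adjusted p ran from 0.00467 to 0.0173 (limma, BH). Their means were 11.8, 7.12, 12.05 and 11.26 in KO and, in the same order, 9.6, 4.86, 9.35 and 7.93 in WT. Hba-a1, from a probe set of its own, read 5.32 ± 0.18 in KO and 5.23 ± 0.10 in WT (SD, n = 4 each). It did not pass (limma, BH adjusted p = 0.713). Both Hba-a1 means lie under the median probe set level of 6.13, where background compresses differences. The Hba-a1 reading therefore cannot count against the rise of the shared probe sets. Of 19 genes of the erythroid and platelet list, 0 were called (median 0.08).

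For the dendritic cell and macrophage genes higher in KO, a lower share of T cells that raises the markers of all other cells alike cannot be told apart from a rise of particular cells. The median of 18 expressed plasmacytoid dendritic cell markers not looked at before lay 0.27 above that of B cell markers (95% bootstrap interval over genes −0.07 to 0.72) and, in a comparison added after that result and the neutrophil median were seen, 0.44 above that of neutrophil markers (0.16 to 0.62; 0.22, 0.11 to 0.55, over all measured markers), but the neutrophil markers read 6.27 to 6.95, near the array median, and markers this dim exclude nothing. The B cell list also leaves out class II genes, Spib and Ly6d, which had been seen to rise, and that can widen the 0.27. More plasmacytoid dendritic cells, which carry CD4 in mouse spleen and so might pass a CD4 sort, stay open. The median of the 21 measured markers (0.23), 0 of which are in the lists fixed earlier, lay at percentile 99.99 of the random lists. That percentile has the limit given above for markers that move together. Atp1b1, the brightest of the 21 on this array, where brightness also depends on the probes, read 9.90 in KO and 10.67 in WT. The bright markers Irf8, Ccr9 and Bst2 read 9.65, 9.36 and 8.76 in KO, but they and the others of a list of 8 expressed markers (median 1.68) were listed for values already seen and are no evidence. Red pulp macrophage markers, 10 of 16 of which are in the myeloid list, stood at percentile 100. The gate's other antibodies are not given in the sources used here, and a change of these genes within T cells through the loss of Ahr, the biological difference of the design, was not tested.

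Genes lower in KO were often called from 1 of several probe sets. For them, RNA quality as a part of the cause cannot be told apart from an effect of genotype. Among the 271 probe sets lower in KO, 62.7% read higher on the WT array numbered 2 than on number 1 in both treatments, against 24.4% of all tested (of the 360 higher, 48.3% read lower on number 2 in both, against 40.0%). These arrays had the lowest actin and Gapdh differences. The actin difference had means of 3.66 in KO and 3.62 in WT (exact permutation p = 0.914). With it as a covariate 271 of the 271 stayed called, with a median of −0.80 before and after. The rule written for that fit asked for means further apart and gave no verdict. Means this close argue against a linear trend with the actin difference as the whole cause for these 271. No fit used the Gapdh difference. Changes limited to 1 probe set, as differences in transcript ends could give, cannot be told apart from changes of the whole gene: over 182 genes the median of the 347 other probe sets was −0.20 (95% bootstrap interval −0.25 to −0.15) against −0.83 for the probe set with the smallest p, a ratio of 0.237, with the sign shared by 82.4% of them at a lower level (mean 6.67 against 7.88). Choosing the probe set with the smallest p on these same arrays itself lowers such a ratio. An earlier form left out other probe sets that were called, which lowers the ratio by construction. It gave a lower ratio that favoured a change limited to 1 probe set, and so decides nothing. For 138 genes higher in KO the medians were 0.24 and 0.73 and the shared sign 80.6%. A loss of whole transcripts through the missing receptor was not tested.

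The array WT TCDD replicate 1 has a description that names the knockout. Among 667 probe sets called between KO and WT without it, its value was nearer the WT mean in 65.2% and nearer the KO mean in 34.8%, which lies under the 75% set in advance for either reading, so a wrong label and a right one cannot be told apart by this test. For the other arrays, tested the same way, the share nearer their own genotype ran from 67.7% (KO DMSO replicate 1) to 100% (KO TCDD replicate 2). In the Tiparp probe set with the largest fall, chosen after its values were seen, it read 7.35, nearer the other WT arrays (7.42 to 7.73) than the KO arrays (6.34 to 6.44), and without it 667 probe sets were called. The difference in genotype itself stays the other open reading.

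Of the 35 splits of the 8 arrays into 4 and 4, 1, the split by genotype, gave 631 called probe sets (limma, BH) and the highest of the others gave 0. This is the smallest share 35 splits can give, and it lies under the share set in advance. Every other split puts arrays of both genotypes in each group, which widens its spread wherever the genotypes differ. The test therefore cannot exclude chance in the grouping. At an unadjusted p under 0.05 the genotype split gave 4641 and the split that exchanges KO DMSO replicate 1 with WT TCDD replicate 1, the array with the conflicting description, 4102. The split by replicate number gave 0 at the adjusted threshold. The count of 631 fell to 362 without KO DMSO replicate 2, 119 without KO TCDD replicate 1, 109 without KO TCDD replicate 2, 420 without WT DMSO replicate 1, 124 without WT DMSO replicate 2 and 126 without WT TCDD replicate 2.

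Further tests were run, of which the first is undecided. Without both WT arrays numbered 2, the median of the 271 probe sets lower in KO went from −0.80 to −0.68 and that of the 360 higher from 0.79 to 0.73, and all kept their sign, which a call with small WT spread largely fixes in advance. Among the 100 measured genes nearest Ahr on its chromosome, order taken from GRCm38.p6, 3 were called (3%) against 398 of 12292 elsewhere (3.24%; Fisher's exact test, two-sided p = 1). With 25 genes per side p was 1, and with 87 genes on 1 side and 100 on the other it was 0.836 (same test). With the chromosome 12 list left out, 627 probe sets were called, so genes of that list are not the source of most calls.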
